A study of Mus musculus with 8 samples.

How the data were processed

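The series holds 8 ear libraries, 4 from mice given MMP-9-IN-1 and 4 from mice given vehicle, grouped by their titles, which number the mice 1 to 4 in each group and so name separate animals. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads and sequenced as single-end reads of 50 bases on a DNBSEQ instrument, and the solvent was 10% DMSO, 40% PEG300 and 50% PBS. The submitters' processing notes name HISAT and the GRCm39 mouse genome build without a version; the counting tool and the annotation are not given in the sources used here. The authors deposited 1 table of 19126 genes with estimated read counts, FPKM and TPM per library, paired with gene symbols. The deposited counts were taken for expected counts, since 33.7% to 35.3% of the values in a library were not whole within a tolerance of 1e-09. The deposited FPKM values, scaled by the authors to gene length and library size, entered 1 alternative, and the deposited TPM values, scaled by the authors to gene length and a fixed total per library, entered no test. A further 6 columns with the authors' group means were not used. The reference tables at hand are of another build, so no coordinates are given; they served to match 5 list names to older symbols and to find 19069 of the gene identifiers, 18934 of them protein coding.

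Expected counts were rounded to whole numbers. Library totals ranged from 13863145 to 18512200 reads. Pairs of libraries of the same group differed by far more than sampling noise, with a chi-square per degree of freedom between 22.8 and 289, so all 8 counted as separate replicates. Genes were kept with edgeR's filterByExpr, which left 15096, and libraries were scaled with TMM factors between 0.815 and 1.08. The median standard error of a log2 fold change was 0.26, and the biological coefficient of variation was 41.0%. CPM values in the text carry the TMM scaling. The main test was edgeR's quasi-likelihood test of inhibitor minus vehicle on all 8 libraries with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Of 39 lists fixed for skin, immune cells and other tissues of the ear, 36 had at least 5 tested members; those for B and plasma cells, eosinophils and sex-linked genes did not and were not tested. The main design, the lists, the rule for named genes and the alternatives not said below to be added were chosen before the data were examined. The rule named Mmp9, genes past the threshold, up to 4 members of each list with the smallest p and, since fewer than 5 genes passed, the 10 genes with the smallest p. Of the list members, the text names the 2 with the smallest p of each list that passed and of the metalloproteinase and chemokine lists, and any other gene was chosen after its values were seen. Separation of the groups was tested by exact one-sided permutation over the 35 splits of 8 libraries into 4 and 4.

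The mouse numbers pair the samples in the sense that same-numbered libraries deviated together. The correlation of their deviations from the group means was 0.397, 0.710, 0.673 and 0.682 for mice 1 to 4, all over 0.1. The pairing comes from these correlations and not from the labels, which do not say that a number marks a shared cage, litter or day. Not every library correlated best with its own number. Inhibitor mouse 3 had 0.685 with vehicle mouse 4 against 0.673 with its own number. Vehicle mouse 1 had 0.554 with inhibitor mouse 2 against 0.397 with its own number. Lower positive values were found between inhibitor mouse 1 and vehicle mouse 2 (0.272) and between inhibitor mouse 4 and vehicle mouse 3 (0.377). The correlations therefore cannot tell a pairing by number from the division between mice 1 and 2 and mice 3 and 4.

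Alternatives were DESeq2 size factors, total counts, no low-count filter, a filter of at least 1 CPM in every library, DESeq2, limma-voom with quality weights, limma-trend on log2(FPKM + 1) for genes with at least 1 FPKM in 4 libraries, the mouse number as a block, each library left out in turn, other thresholds, camera with an estimated correlation and fry. Fits to mice 1 and 2 only, to mice 3 and 4 only and with that division as a covariate, the block with an estimated correlation, the block with each mouse number left out of both groups, differences within same-number pairs, exact permutation of list means, the respiratory chain list without muscle isoforms estimated correlations within mice 1 and 2 and within mice 3 and 4, distances without the division or without all mouse numbers, and splits that part every same-number pair were added after seeing the data. On simulated counts for the 15096 genes of this comparison, 50 genes were changed at each fold, with the average spread of the real fit at each expression level. There edgeR recovered 0% of genes changed 1.5-fold, 24.0% at 2-fold, 76.0% at 4-fold and 98.0% at 8-fold, with 2 false calls. With the smaller spread left once the mouse-number division is fitted, it recovered 2.00%, 70.0%, 96.0% and 98.0% at these folds, with 9 false calls. The simulated counts held no mouse-number division and gave no gene a spread of its own. These shares therefore do not hold for genes that spread more, such as Mmp10, which was not called at a log2 fold change of -3.62 (SE 2.14). On simulated counts of independent genes with no change, camera called 0 lists, and with the neutrophil list doubled it called 1. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.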

Results

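RNA was sequenced from the left ears of 8 C57BL/6 mice, an inbred laboratory strain, in a model of allergic contact dermatitis, a skin inflammation that follows repeated contact with a sensitising chemical. The mice were 6 to 8 weeks old. Dinitrofluorobenzene (DNFB), the sensitiser, was first given to every mouse as 25 µL of a 0.3% solution, and from day 6 the left ear received 10 µL of a 0.25% solution. In the inhibitor group, 4 mice were injected into the peritoneum with 10 mg/kg MMP-9-IN-1, an inhibitor of the secreted protease matrix metalloproteinase 9 (MMP-9, gelatinase B). In the vehicle group, 4 mice received the solvent. The treatment went on for 4 days before the ears were taken. The comparison asks how blocking MMP-9 alters gene expression in the inflamed ear. Ears without DNFB were not analysed here. The 8 libraries held between 13863145 and 18512200 counted reads, and between 17028 and 17629 genes had at least 1 read. The 10 most abundant genes took from 5.07% to 7.03% of the reads, led by the keratins Krt14 and Krt5, the ferritin gene Fth1 and the elongation factor gene Eef1a1.

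Between inhibitor and vehicle ears no gene passed the threshold. Among the 10 genes with the smallest p, Pmel, which encodes the fibrils of the pigment granule, had 4.75 ± 1.56 CPM (SD, n = 4) with the inhibitor against 11.99 ± 2.46 CPM with vehicle. Sprr2b, a cornified envelope gene, had 0.710 ± 0.194 against 1.92 ± 0.456 CPM. Lama3, a laminin chain of the epidermal basement membrane, had 53.7 ± 4.24 against 78.4 ± 16.4 CPM, and Abca12, the lipid transporter of epidermal lamellar granules, had 16.4 ± 1.21 against 35.4 ± 18.3 CPM. Etv5, a transcription factor of the ETS family, was on the higher side at 33.96 ± 10.1 against 21.0 ± 0.767 CPM.

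Of 15096 genes tested with edgeR's quasi-likelihood test, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 157 genes, 57 higher and 100 lower with the inhibitor. DESeq2 and limma-voom also called 0 genes, with 293 and 296 at an unadjusted p under 0.05. With the mouse number as a block, edgeR called 0 genes and 724 had an unadjusted p under 0.05. If nothing changed, a share of 0.05 of the 15096 genes would have such a p by chance. The 157 genes of the main test lay well below that share and the 724 of the block close to it, so the rise is no gain in signal. The main fit counts differences between mouse numbers as spread, which makes it a cautious test. The 10 genes with the smallest unadjusted p in edgeR were Pmel (log2 fold change -1.33, SE 0.29), Lancl3 (-1.95, SE 0.42), Sprr2b (-1.43, SE 0.32), Zfp991 (0.46, SE 0.12), Dok4 (-0.53, SE 0.15), Ccdc13 (-1.20, SE 0.33), Etv5 (0.69, SE 0.20), Gm14308 (0.86, SE 0.25), Lama3 (-0.55, SE 0.16) and Abca12 (-1.11, SE 0.33). In each of these 10 genes the 4 libraries of 1 group lay wholly above those of the other. This held for 180 of the tested genes, or 1.19%, where chance gives 2.86%. Sprr2b, Zfp991 and Gm14308 belong to families of closely similar genes, so their reads can be shared with other copies and their values are uncertain.

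Mmp9 itself, the gene of the inhibited protease, was high in some ears of both groups. It had 249.9, 259, 8.15 and 17.1 CPM in vehicle mice 1 to 4 and 10.1, 113, 11.96 and 21.8 CPM in inhibitor mice 1 to 4. The group means were 133 ± 139.6 CPM with vehicle and 39.3 ± 49.7 CPM with the inhibitor (SD, n = 4). The log2 fold change was -1.76 (SE 1.23, edgeR adjusted p = 0.999), so the difference lay within the spread between mice. An inhibitor acts on the protein and need not alter the transcript, so this value does not check the group labels. The estimate was -2.03 among mice 1 and 2 and 0.39 among mice 3 and 4, 0.29 with limma-voom quality weights and -3.22 without inhibitor replicate 2. Leaving out 1 library without a block unbalances the mouse numbers between the groups. Such shifts and lost calls, here and below, therefore mix that imbalance with the influence of the library itself.

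The list of matrix metalloproteinases and their tissue inhibitors did not pass the test. Of its 22 tested members, 9 had a higher and 13 a lower estimate, with a mean log2 fold change of -0.51 (camera adjusted p = 0.513). Mmp13, a collagenase, had a log2 fold change of -3.19 (SE 1.82), and Mmp10, a stromelysin, one of -3.62 (SE 2.14), both with an edgeR adjusted p of 0.999. Their vehicle means came from mice 1 and 2, with Mmp13 at 347 and 981 CPM there and at 3.95 and 8.35 CPM in vehicle mice 3 and 4. Their inhibitor means came mostly from mouse 2, with 126 CPM for Mmp13 and 38.9 CPM for Mmp10. Over the other tools, scalings and filters, the block and left-out libraries, the estimates ran from -5.63 to 0.19 for Mmp13 and from -6.76 to 0.29 for Mmp10. Without inhibitor replicate 4 the list passed (mean -0.64, adjusted p = 0.0347), while its mean was -0.28 without vehicle replicate 2, -0.33 without inhibitor replicate 1 and -1.02 without inhibitor replicate 2. The list of other proteases passed, with 18 of 28 members lower, a mean of -0.42 and a camera adjusted p of 0.000497. The adjusted p was 0.462 with an estimated correlation. Its first members were the kallikreins Klk5 (-0.93, SE 0.28) and Klk8 (-1.17, SE 0.48), serine proteases of the outer epidermis. Without inhibitor replicate 1 its call was lost (mean -0.27, adjusted p = 0.268), and without vehicle replicate 2 the mean was -0.26.

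**Figure D1:**
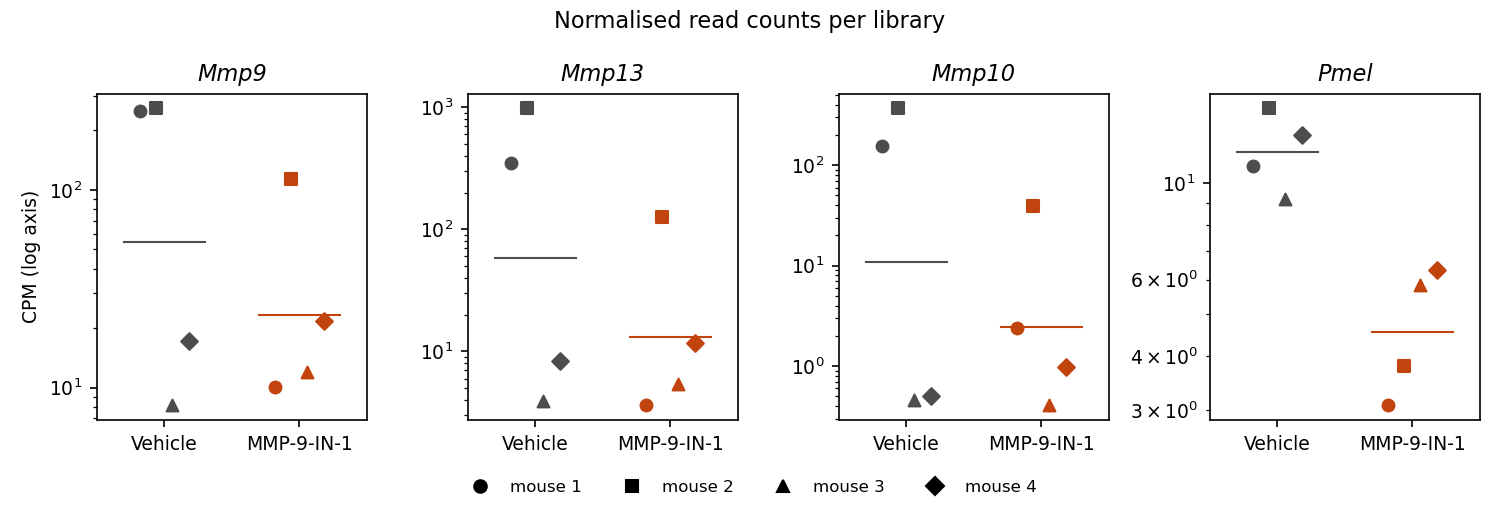
Normalised read counts (CPM, log axis) of Mmp9, Mmp13, Mmp10 and Pmel in each library, with vehicle in grey, inhibitor in orange, a marker shape per mouse number and a line at the geometric mean of each group. Mmp9 reaches 259 CPM in a vehicle ear and 113 CPM in an inhibitor ear, while the 4 Pmel values with the inhibitor lie below the 4 with vehicle.

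Neutrophil and inflammatory cytokine genes were lower on average in the inhibitor ears. All 21 tested neutrophil markers had a lower estimate, with a mean log2 fold change of -1.18, as did 24 of 27 cytokine genes, with a mean of -1.13. Ly6g, a surface protein of mouse neutrophils, had 6.28 ± 8.02 CPM with the inhibitor against 28.0 ± 31.0 CPM with vehicle, and Ltf, which encodes the granule protein lactoferrin, 0.799 ± 0.478 against 1.87 ± 1.82 CPM (SD, n = 4). Among the cytokines, Il1f9 and Il1f6, which encode the interleukin-36 cytokines of stressed epithelium, had log2 fold changes of -1.58 (SE 0.68) and -1.43 (SE 0.53). The means moved with 1 library left out, which unbalances the mouse numbers between the groups. Without vehicle replicate 2 they were -0.67 for neutrophil markers and -0.61 for cytokines, and without inhibitor replicate 2 they were -2.45 and -2.11. No member of either list passed the threshold, over all genes or adjusted over the list alone.

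Both lists passed camera with its preset correlation, at an adjusted p of 9.41e-08 for neutrophil markers and 9.71e-09 for cytokines. The adjusted p was 0.462 for each with an estimated correlation. In an exact two-sided permutation test of the mean of the list per library, p was 0.371 for each. The vehicle mean of the neutrophil list came from libraries that stood apart by mouse number: it was 7.87 and 8.18 log2 CPM in vehicle mice 1 and 2, and 4.32 and 4.95 in mice 3 and 4. Among mice 1 and 2 the neutrophil list had a mean log2 fold change of -1.42 and the cytokine list of -1.46, and among mice 3 and 4 of 0.03 and 0.18.

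Genes of activated epidermis, tissue stress and red blood cells had lower mean estimates over all 8 ears but not among mice 3 and 4, where their means were 0.055, 0.33 and 0.66. There the stress and red blood cell lists passed camera as higher (adjusted p = 0.000531 and 0.00259), and the adjusted p was 0.899 for each with an estimated correlation. No member of these lists passed the threshold. Activated-keratinocyte genes had a mean log2 fold change of -0.96, with 23 of 27 members lower (camera adjusted p = 2.24e-05). The adjusted p was 0.462 with an estimated correlation, and without vehicle replicate 2 the preset call was lost (mean -0.46, adjusted p = 0.0870). Sprr1b, a cornified envelope precursor, stood at 85.5 ± 57.4 CPM with the inhibitor and 566 ± 723 CPM with vehicle. The immediate early and heat shock list, which can rise with tissue handling, had 18 of 19 members lower, a mean of -1.08 and a camera adjusted p of 2.48e-07, and the adjusted p was 0.462 with an estimated correlation. Hspa1b and Hspa1a, the inducible heat shock protein genes, had log2 fold changes of -1.503 (SE 0.58) and -1.56 (SE 0.63). As near-identical copies they share reads, so their separate values are uncertain. All 6 red blood cell genes were lower, with a mean of -2.34 (camera adjusted p = 0.000359), and the adjusted p was 0.462 with an estimated correlation. Alas2, the first enzyme of haem synthesis in red cell precursors, had -2.48 (SE 1.22) and Hba-a1, an alpha globin gene with a near-identical copy, -2.64 (SE 1.5). Without inhibitor replicate 2 the means were -3.68 for red cell and -1.47 for activated-keratinocyte genes, and without vehicle replicate 2 the immediate early mean was -0.55.

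Genes for oxidative stress and low oxygen also had lower mean estimates over all 8 ears but not among mice 3 and 4, where the means were 0.019 and 0.0011. The oxidative stress list had 18 of 20 members lower, a mean log2 fold change of -0.55 and a camera adjusted p of 0.000592, and the adjusted p was 0.462 with an estimated correlation. Gclc and Gclm, the subunits of the rate-limiting enzyme of glutathione synthesis, had -0.66 (SE 0.45) and -0.58 (SE 0.39). The hypoxia and angiogenesis list had 14 of 19 members lower, a mean of -0.55 and a camera adjusted p of 0.00673, and the adjusted p was 0.538 with an estimated correlation. Adm, which encodes the vasodilator adrenomedullin, had -2.52 (SE 1.17), and Ndrg1, a gene induced by low oxygen, -0.97 (SE 0.48). Without vehicle replicate 2, neither list passed the preset test, with means of -0.30 (adjusted p = 0.0537) and -0.15 (adjusted p = 0.689), and the hypoxia list also failed without inhibitor replicate 3 (-0.40, adjusted p = 0.116).

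The mean of the melanocyte genes was lower in each of the 4 inhibitor ears than in any vehicle ear. The 7 tested markers all had a lower estimate, with a mean log2 fold change of -0.74, and 2 of them passed when adjusted over the list alone, while 0 passed over all genes. Pmel had -1.33 (SE 0.29) and Mlana, a melanosome protein gene, -1.15 (SE 0.37), with 1.89 ± 0.664 CPM with the inhibitor against 4.21 ± 1.71 CPM with vehicle. The list passed camera at an adjusted p of 2.55e-10, and the adjusted p was 0.346 with an estimated correlation. In an exact two-sided permutation test of the list mean per library, p was 0.0286, the smallest that 4 against 4 allows, which adjustment over the 36 lists could keep under 0.05 only if most lists reached it. The gap was narrow, with at most 2.20 log2 CPM in the inhibitor ears and at least 2.24 in the vehicle ears. Of the 36 lists only 1 had an exact p under 0.05. Chance sets a list fully apart in 2.86% of cases, so 1 such list among 36 is no more than chance can give. That permutation takes no account of the mouse numbers, and within same-number pairs an exact permutation p cannot go below 0.125. The mean was -1.31 among mice 1 and 2 and -0.37 among mice 3 and 4.

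Epidermal barrier and hair follicle genes had lower mean estimates by smaller amounts. Of 32 barrier genes 27 were lower, with a mean log2 fold change of -0.38 (camera adjusted p = 3.28e-05), and the adjusted p was 0.462 with an estimated correlation. Calm4, a calcium-binding protein of differentiating keratinocytes, had -0.68 (SE 0.26), and Tgm3, a transglutaminase that cross-links the cornified envelope, -0.79 (SE 0.34). The barrier call was lost without vehicle replicate 3 (mean -0.18, adjusted p = 0.0666) and without inhibitor replicate 1 (mean -0.15, adjusted p = 0.197), and among mice 1 and 2 (mean -0.21, adjusted p = 0.0765). The barrier mean was -0.59 without vehicle replicate 1, -0.18 without vehicle replicate 4 and -0.67 without inhibitor replicate 3. Of 9 tested hair follicle genes 6 were lower, with a mean of -0.39 (camera adjusted p = 0.0103), and the adjusted p was 0.462 with an estimated correlation. Foxn1, the transcription factor lost in nude mice, had -0.56 (SE 0.20) and Lef1, a mediator of Wnt signalling in the follicle, -0.40 (SE 0.20). The hair call was lost without vehicle replicate 4 (adjusted p = 0.0641), without inhibitor replicate 2 (adjusted p = 0.146) or 4 (adjusted p = 0.0553), and among mice 1 and 2 (mean -0.40, adjusted p = 0.0658).

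Skeletal muscle, fat, sebaceous gland, respiratory chain and cell cycle genes had higher mean estimates in the inhibitor ears. All 27 muscle genes had a higher estimate, with a mean log2 fold change of 1.11 (camera adjusted p = 2.55e-10), and the adjusted p was 0.462 with an estimated correlation. Mb, the myoglobin gene, had 304 ± 159 CPM with the inhibitor against 154 ± 65.2 CPM with vehicle, and Acta1, skeletal muscle actin, 739 ± 421 against 342 ± 148.0 CPM (SD, n = 4). In the exact permutation test of the list mean, p was 0.486, and among mice 1 and 2 the mean was 0.56 (adjusted p = 0.286). Without inhibitor replicate 4 it was 0.72. The respiratory chain list had 25 of 27 members higher and a mean of 0.24 (camera adjusted p = 1.12e-05), and the adjusted p was 0.462 with an estimated correlation. Ndufs1 and Ndufa1, subunits of complex I, had 0.31 (SE 0.13) and 0.27 (SE 0.13). Without its striated muscle isoforms Cox6a2, Cox7a1 and Cox8b, chosen after seeing the data, the mean was 0.15 and the list still passed at the preset correlation.

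Of 21 sebaceous gland genes 19 were higher, with a mean log2 fold change of 0.31 (camera adjusted p = 3.28e-05), and the adjusted p was 0.462 with an estimated correlation. Mgst1, a membrane glutathione transferase, had 0.36 (SE 0.23) and Cidea, a lipid droplet protein gene, 0.48 (SE 0.33). The sebaceous mean was 1.12 among mice 1 and 2 and -0.16 among mice 3 and 4, and it was 0.14, 0.15 and 0.56 without vehicle replicates 1, 2 and 3. Adipocyte genes had 15 of 16 members higher and a mean of 0.43 (camera adjusted p = 0.000762), and the adjusted p was 0.538 with an estimated correlation. Cfd, the fat cell product adipsin, had 0.75 (SE 0.49) and Adig, adipogenin, 0.70 (SE 0.49). Without inhibitor replicate 4 the adipocyte call was lost (mean 0.08, adjusted p = 0.119), as it was on FPKM values with limma-trend (adjusted p = 0.0678), and the mean was 0.19 without vehicle replicate 1 or 2 and 0.86 without vehicle replicate 4. Cell cycle genes had 21 of 24 members higher and a mean of 0.14 (camera adjusted p = 0.000899), and the adjusted p was 0.688 with an estimated correlation. Tyms, the thymidylate synthase gene, had 0.32 (SE 0.12) and Cdk1, the mitotic kinase gene, 0.27 (SE 0.16). The cell cycle call was lost without vehicle replicate 1 (mean 0.02, adjusted p = 0.232) and without vehicle replicate 2 (mean 0.05, adjusted p = 0.0515), and the mean was 0.31 without vehicle replicate 3 and 0.078 without inhibitor replicate 3.

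**Figure D2:**
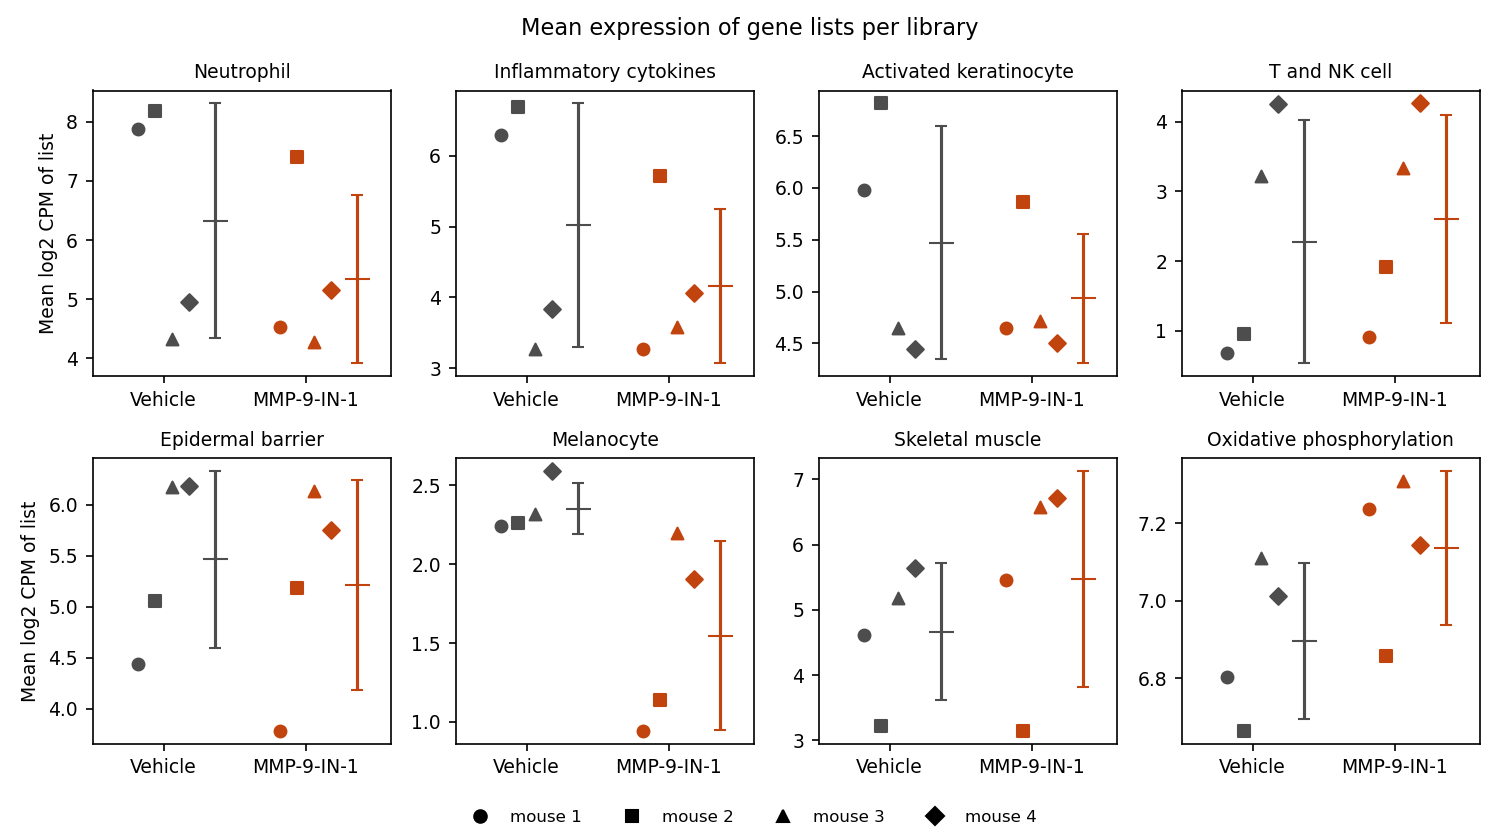
Mean log2 CPM of the members of 8 gene lists in each library, with vehicle in grey, inhibitor in orange, a marker shape per mouse number, and the mean and SD of each group (n = 4) at its right. The neutrophil list spans 4.32 to 8.18 within the vehicle group, and the melanocyte list is at or below 2.20 in the inhibitor ears and at or above 2.24 in the vehicle ears.

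In all, 16 of the 36 lists with at least 5 tested members passed camera with its preset correlation, 5 higher and 11 lower, while 0 passed with an estimated correlation and 0 passed fry. Over these 16 lists the estimated correlation ran from 0.0453 for hair follicle to 0.960 for red blood cell genes, above the preset 0.01. The preset p-values take the genes of a list as nearly independent and are too small where they move together. With limma-voom quality weights 6 passed, 4 of them among the 16 (epidermal barrier, skeletal muscle, melanocyte and respiratory chain), while type I interferon genes passed as lower (-0.20) and type 2 immune genes as higher (0.36). That fit had no block and weighted the mouse numbers differently in each group, so its estimates can carry part of the mouse-number division. Among mice 3 and 4 only, 12 of the 21 lists followed had the opposite sign to that over all 8 ears. Of these 12, 7 passed camera in that direction, namely the stress and red blood cell lists, other proteases (0.20, adjusted p = 0.0403), metalloproteinases (0.28, adjusted p = 0.0388), chemokines (0.43, adjusted p = 7.01e-05), cell cycle genes (-0.10, adjusted p = 0.0484) and sebaceous gland genes (-0.16, adjusted p = 0.0112), and 0 lists passed there with an estimated correlation.

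Among the lists that did not pass were T and NK cell markers (mean log2 fold change 0.09, camera adjusted p = 0.425), MHC class II genes (0.12, adjusted p = 0.568), collagens and matrix genes (0.16, adjusted p = 0.126) and chemokines (-0.30, adjusted p = 0.425). Among mice 1 and 2 only, camera called chemokines as lower (-0.56, adjusted p = 0.0143) and T and NK cell markers (0.67, adjusted p = 0.0143) and MHC class II genes (0.88, adjusted p = 0.0322) as higher, and the adjusted p was 0.852 for each with an estimated correlation. With the mouse number as a block, camera called the first 3 of these as higher, T and NK cell markers at 0.27 (adjusted p = 0.00246), MHC class II genes at 0.27 (adjusted p = 0.0230) and matrix genes at 0.20 (adjusted p = 0.0139). With the block and an estimated correlation the adjusted p was 0.725, 0.735 and 0.725. With mouse number 2 left out of both groups in the blocked fit, an alternative added after seeing the data, T and NK cell markers were at 0.056 (adjusted p = 0.380) and MHC class II genes at 0.035 (adjusted p = 0.513), and with mouse number 4 left out matrix genes were at 0.14 (adjusted p = 0.262). The mean log2 CPM of the list was higher with the inhibitor in all 4 same-number pairs, also compared after seeing the data, for T and NK cell, MHC class II, adipocyte and respiratory chain genes, though for the first 2 of these lists the pair of mouse 4 differed by only 0.0034 and 0.014. Melanocyte and glucocorticoid genes were lower in all 4 pairs. For a single list, all 4 pairs lie on the higher side by chance in 6.25% of cases, and an exact paired permutation test cannot go below a p of 0.125. Without the block, leaving out 1 library unbalances the mouse numbers, and the 3 means ran from -0.66 to 0.98, from -0.47 to 0.83 and from -0.21 to 0.46. All 3 lists passed as higher without vehicle replicate 4 (adjusted p = 0.000147, 0.0136 and 0.000573) and without inhibitor replicate 1 (adjusted p = 0.000919, 0.00931 and 0.000191), and matrix genes also without inhibitor replicate 3 (adjusted p = 0.0196). Without inhibitor replicate 4, T and NK cell markers and matrix genes passed as lower (adjusted p = 0.0276 and 0.0267). Chemokines passed without inhibitor replicate 4 (-0.41, adjusted p = 0.0215). Among the chemokines, Cxcl10, an interferon-induced ligand of a chemokine receptor on T cells, had -0.48 (SE 0.31) and Cxcl12, a stromal ligand, 0.72 (SE 0.52). Monocyte and macrophage (0.07), dendritic cell (-0.10), mast cell (0.23), fibroblast (0.04), endothelial (0.06), Schwann cell (-0.07) and cartilage (0.21) markers did not pass, nor did type I interferon (0.02), interferon-gamma (-0.02), type 2 immune (-0.09), itch (-0.29), TGF-beta (-0.10), basal keratinocyte (-0.11), circadian clock (-0.19) and glucocorticoid (-0.25) genes. Of these, interferon-gamma genes passed as lower among mice 1 and 2 (-0.35, adjusted p = 0.0497) and as higher among mice 3 and 4 (0.24, adjusted p = 7.01e-05). Among mice 3 and 4 the monocyte and macrophage (0.42), mast cell (0.24), endothelial (0.24), cartilage (0.33) and type 2 immune (0.43) lists also passed as higher, as did matrix genes (0.25), and basal keratinocyte genes as lower (-0.23). None of these lists passed within mice 1 and 2 or within mice 3 and 4 with an estimated correlation. The mean and the median differed in sign for the interferon-gamma, type 2 and TGF-beta lists, and the mean and the direction of camera for the type I interferon and fibroblast lists.

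The libraries as a whole differed more by mouse number than by treatment. On the 500 most variable genes, the mean distance in log2 CPM was 55.7 between the groups and 60.9 within them. The difference of -5.15 had an exact one-sided permutation p of 0.657, with 23 of the 35 splits giving a difference as large, and it was 0.732 without vehicle replicate 3 and 1.45 without vehicle replicate 4. That permutation takes no account of the mouse numbers. Over only the 8 splits that part every same-number pair, 3 gave a difference as large (exact one-sided p = 0.375, where 8 splits allow no less than 0.125). With the division between mice 1 and 2 and mice 3 and 4 removed the sign turned, to 1.07 (one-sided permutation p = 0.257), and with all mouse numbers removed it was 4.10, with 4 of the 8 splits as large. The p of 0.257 was taken over all 35 splits, some of which follow the removed division, so it is not exact. These 3 alternatives were added after seeing the data. The split with the largest difference, 38.8, set mice 1 and 2 of both groups against mice 3 and 4 of both groups. The first principal component held 74.4% of the variance and the second 15.4%. Inhibitor mouse 1 stood apart on the second component at -40.3.

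**Figure D3:**
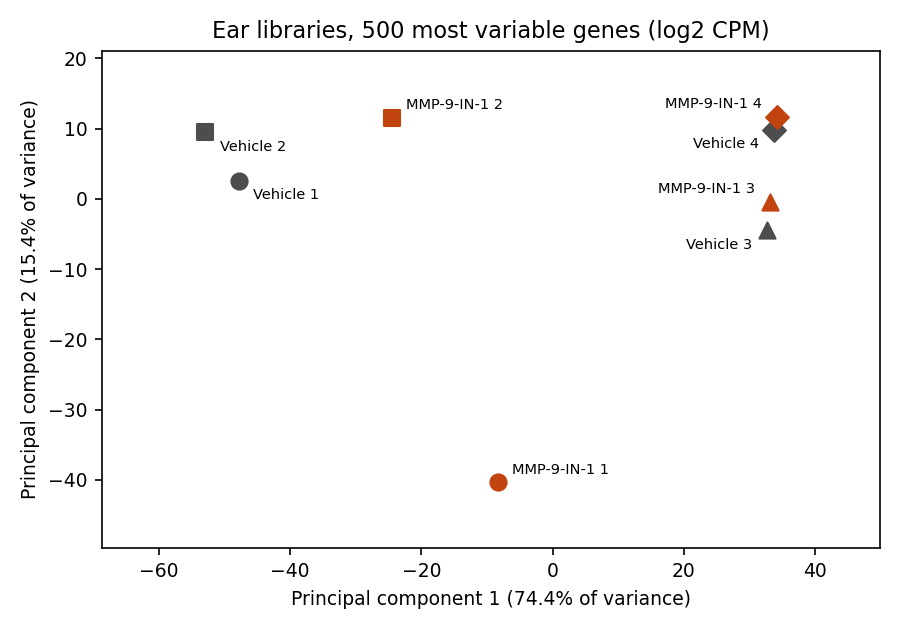
Principal components of log2 CPM over the 500 most variable genes, with each point a library, vehicle in grey, inhibitor in orange and a marker shape per mouse number. Mice 3 and 4 of both groups lie between 32.7 and 34.2 on the first component, and mice 1 and 2 of both groups lie below 0.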

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

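For each named gene, each described list and the library totals, a library was looked for whose gap to its nearest neighbour took more than 0.829 of its group's range, the 95% limit for 4 values. Of 134 groups of values, 8 held such a library, and chance alone gives about 1 in 20. In the inhibitor group, mouse 1 had the lowest Dok4 (3.53 log2 CPM, next 3.84, gap share 0.871) and the highest Etv5 (5.62, next 4.93, gap share 0.850), mouse 2 had the lowest Acta1 (7.08, next 9.71, gap share 0.863) and the highest mean of the activated-keratinocyte list (5.86, next 4.72, gap share 0.842), and mouse 4 had the lowest Mgst1 (8.24, next 8.68, gap share 0.868). In the vehicle group, mouse 3 had the highest Cdk1 (6.50, next 6.17, gap share 0.852), mouse 4 the highest Cfd (5.84, next 4.57, gap share 0.906) and mouse 2 the lowest Mb (5.86, next 7.40, gap share 0.854). No explanation was tested for these single values.

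Other groupings of the libraries were compared with the real one. The test for the genes was set after their count was seen. Since the real split called 0 genes, all 35 of the 35 splits into 4 and 4 gave at least as many by construction, which says nothing about chance. The highest other split called 5809 genes; it set mice 1 and 2 of both groups against mice 3 and 4, while every other split called 0, which points to a structure of the samples. For the lists, 30 of the 35 splits gave at least as many as the 16 of the real split. The other splits called a median of 19 lists and at most 26, so a count of 16 is no more than arbitrary groupings of these libraries give. Among the 8 splits that part all mouse-number pairs, as the real one does, the other splits called between 10 and 17 lists and 5 of them called at least 16.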

How the results depend on the processing

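The fits within mouse numbers, the division as a covariate, the block with an estimated correlation or with a mouse number left out of both groups, the permutation of list means and the separation with mouse numbers taken into account were chosen after seeing the data. The count of genes past the threshold was 0 under every alternative run, including each library left out, while genes at an unadjusted p under 0.05 numbered 157 in the main test, 239 without a low-count filter, 293 with DESeq2, 296 with limma-voom, 724 with the replicate block, 771 with the mouse-number division as a covariate, 2515 in mice 1 and 2 only, 558 in mice 3 and 4 only and from 42 to 433 with a library left out. The 724 and the 771 lie close to the share of 0.05 of the tested genes that chance would give. The 2515 in mice 1 and 2 only lie above it, though genes that move together can raise such a count. Of the 16 lists, 0 passed with an estimated correlation, 0 with fry and 0 with the block and an estimated correlation, and 4 with limma-voom quality weights, which called 6 lists in all. The replicate block gave 19 lists, adding only T and NK cell, MHC class II and matrix genes, gave -1.03 for Mmp9 and changed no other call. Exact permutation of list means also gave 0 after adjustment, but with a smallest possible p of 0.0286 over 36 lists this was nearly fixed by the design. With a mouse number left out of both groups, the blocked fit gave from 15 to 22 lists; without mouse number 1 it gave -0.25 for neutrophils, -0.18 for cytokines, -0.079 for red blood cells and -0.13 for Mmp9, the calls of cytokines, red blood cells, other proteases (-0.0091), cell cycle (0.037) and sebaceous gland (0.20) genes were lost, and the sign turned for chemokines (0.22, with a call as higher) and metalloproteinases (0.037). Calls of the main test were also lost without mouse number 2 for cell cycle (0.12), red blood cell (-0.68) and hypoxia (-0.22) genes and without mouse number 4 for hair follicle genes (-0.28). With a library left out, from 13 to 25 lists passed, and 25 did so without inhibitor replicate 4. These fits had no block, so they mix the influence of a library with unbalanced mouse numbers. Left-out libraries moved Mmp9 from -3.22 to -1.24, chemokines from -0.84 to 0.0030, matrix genes from -0.21 to 0.46, MHC class II genes from -0.47 to 0.83, T and NK cell markers from -0.66 to 0.98 and the separation of the groups from -8.54 to 1.45, and the separation was 1.07 once the mouse-number division was removed and 4.10 once all mouse numbers were, in a replicate block. With limma-voom, which weighted vehicle mice 1 and 2 at 0.333 and 0.316 and inhibitor mouse 3 at 3.36, the sign turned for Mmp9 (0.29), Adm (0.083), Alas2 (0.39), Hba-a1 (0.82), Ltf (0.058), Ly6g (0.23), Mmp10 (0.29) and Mmp13 (0.19). It also turned for the lists of oxidative stress (0.062), chemokines (0.27), red blood cells (0.75), immediate early genes (0.27), activated keratinocytes (0.12), MHC class II (-0.22), metalloproteinases (0.13), other proteases (0.031), cytokines (0.16) and T and NK cells (-0.28). With an estimated correlation, 0 lists passed in mice 1 and 2 only and 0 in mice 3 and 4 only. In mice 3 and 4 only, the sign turned for Mmp9 (0.39) and for the lists of oxidative stress (0.019), chemokines (0.43), red blood cells (0.66), hypoxia (0.0011), immediate early genes (0.33), activated keratinocytes (0.055), metalloproteinases (0.28), neutrophils (0.033), other proteases (0.20), cytokines (0.18), cell cycle (-0.10) and sebaceous gland (-0.16). The voom weights of mice 1 to 4 were 0.333, 0.316, 2.61 and 2.03 with vehicle and 0.480, 1.05, 3.36 and 1.05 with the inhibitor. That fit had no block, so its estimates can carry part of the mouse-number division. T and NK cell and MHC class II genes, negative with voom, were at 0.67 and 0.88 within mice 1 and 2. Within mice 3 and 4 they were at 0.014 and 0.0082, so unequal weights can have turned these signs. The cause of the turns was not tested further. Other scalings moved the median log2 fold change by -0.02 and 0.09 and turned no sign among the 45 genes and 21 lists followed.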

Other observations

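Mice 1 and 2 of both groups differed from mice 3 and 4 of both groups in several immune genes and in the epidermal gene Krt1, all named after their values were seen. Csf3, the neutrophil growth factor gene, had 449 and 349 CPM in vehicle mice 1 and 2 and 5.82 and 161 CPM in inhibitor mice 1 and 2, against 0.820 to 2.56 CPM in the other 4 ears. Il6 had 171, 263, 22.2 and 94.1 CPM in the same 4 ears and at most 8.61 CPM in the others. The terminal differentiation gene Krt1 had 90.3, 109, 133 and 400.2 CPM there, and from 745 to 1303 CPM in mice 3 and 4. Not every epidermal gene parted these mice, since the keratin gene Krt14 had 7083 CPM in inhibitor mouse 4 and from 6973 to 9124 CPM in mice 1 and 2. Cd3e, a T cell receptor component, was at most 1.37 CPM in mice 1 and 2 and from 4.80 to 10.7 CPM in mice 3 and 4, and the MHC class II gene H2-Aa at most 347 CPM against 692 to 1266 CPM. Ccl21a, the lymphatic chemokine gene, had between 6.51 and 56.9 CPM in mice 1 and 2 and between 94.9 and 246 CPM in mice 3 and 4, and its copies Gm13304 and Gm13309 can share its reads. The Y-linked genes Ddx3y, Kdm5d and Eif2s3y stood at or below 0.275, 0.0689 and 0.685 CPM in all 8 ears.

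The tests of a tissue share and of blood were chosen only after the results were seen, and after a first run their SE was changed from that over list members to that between libraries, because genes of a list are not independent. The division by mouse number called 5809 genes with edgeR, 2816 higher and 2993 lower in mice 3 and 4. Sequencing depth was argued against, since thinning every library to the smallest total still left 5606 calls. A lower share of the main tissue on 1 side, which would raise other cell types alike, was argued against too: in mice 3 and 4 the T and NK cell list was higher by 2.66 (SE 0.40) and the neutrophil list differed by -2.32 (SE 0.87), 4.98 apart (SE 0.86), or 5.52 (SE 0.44) over list members. The inhibitor cannot divide the vehicle mice, and no biological explanation was tested. Whether the numbers mark cohorts, harvest days or library batches is not stated in the labels and stays open.

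The lower neutrophil and cytokine lists appeared in mice 1 and 2 and not in mice 3 and 4, and more in mouse 1, with same-number differences of -3.34 and -3.02, than in mouse 2, with -0.78 and -0.97. In the blocked fit the means were -0.94 and -0.78, and -0.25 and -0.18 without mouse number 1. A candidate explanation is an inhibitor effect that differs between these mice, but permuting the group labels within mice 1 and 2 and within mice 3 and 4 gave an exact two-sided p of 0.111, and the 36 assignments allow no less than 0.0556. edgeR's interaction test called 0 of 15096 genes. It had 2659 at an unadjusted p under 0.05, above the share of 0.05 that chance would give. Genes that move together can raise such a count, so it does not decide the question. Over lists, the difference of mice 3 and 4 from mice 1 and 2 in the inhibitor effect averaged 1.55 for neutrophil and 1.72 for cytokine genes. The camera adjusted p was 4.09e-05 for neutrophil genes at the preset correlation, but 0 lists passed with an estimated correlation. More blood in the vehicle ears of mice 1 and 2 may contribute, as the red cell genes followed the same libraries. The test took the activated-keratinocyte list as one that blood leaves alone. That need not hold for members such as Lcn2 and Slpi, which neutrophils can also express, so the list is not a clean control. Its mean was -1.14 in inhibitor minus vehicle there, which argued against blood when judged over list members (-1.15, SE 0.26). With the SE of 0.74 between libraries that verdict was lost, and the explanations cannot be told apart.

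The higher skeletal muscle list may reflect more muscle in the ear pieces of the inhibitor group. In that case the 27 genes would keep their ratios, and a common level per library explained 76.5% of their variance, against 10.9% at the 95th percentile of 1000 random lists matched on expression. The limits set beforehand were 80% for and 50% against, so this test left the explanation open. An effect of the inhibitor on all muscle genes would also give a common level per library, so the test cannot tell the 2 apart. Variation between ears that has nothing to do with the inhibitor is open too. The exact two-sided permutation p of the list mean was 0.486, and in the pair of mouse 2 the list differed by -0.073.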
